A study of Mus musculus with 12 samples.

How the data were processed

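RNA was sequenced from lens epithelial cells left on the lens capsule of 2 month old mice after the fiber cell mass of the lens had been removed, a mouse model of cataract surgery. Capsules were collected at 0 h, directly after fiber cell removal, or 48 h later. Wild type (WT) mice were C57BL/6. The FNcKO mice, which carry a conditional knockout of the fibronectin gene Fn1, had a mixed background of C57BL/6, 129 and FVB/N, so genotype and strain background coincide in every comparison between them. The labels put 12 libraries into 4 groups of 3, which are WT at 0 h, WT at 48 h, FNcKO at 0 h and FNcKO at 48 h. The design text calls the replicates of a group biological triplicates; how many lenses or animals entered a library is not given in the sources used here. Per the labels' protocols, stranded TruSeq libraries were made from total RNA and read on a HiSeq instrument.

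The authors deposited, for each library, a whole-number read count for each of 24147 genes together with gene coordinates and coding length. The submitters' processing notes list FastQC, Trim Galore 0.4.4, TopHat2 2.1.0, SAMtools 1.4, bedtools 2.17, HTSeq 0.6.1p1 and edgeR 3.16.5 with the mm10 build, without roles, order or options; the annotation, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. The deposited files also hold an RPKM value per gene, per the file headers. It equals the count divided by coding length and by the summed counts of the library, with a largest relative difference of 5.3e-15, and was used only for this check. Some 163 entries had a symbol that occurred more than once, held at most 0.163% of a library's counts and were kept as separate entries. Reads of close paralogs, such as the Serpina3 and the gamma crystallin genes, can be split or dropped by such counting, so values of single members are less certain than those of their sums.

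A combined table deposited with the series holds 9 of the libraries, and 8 of its count columns equal the file of the library they are named for. The column named for WT 0 h replicate 1 instead equals the file of FNcKO 0 h replicate 1 in all 24147 genes. The file of WT 0 h replicate 1 itself was used throughout. Gm9199 and Bst1 were chosen for a check after their values were seen, from a fit that held this library among the WT libraries. It held 199 counts of Gm9199 and 1333 counts of Bst1, while the other WT 0 h libraries held 114 and 108 counts of Gm9199 and 1080 and 1528 of Bst1, and no FNcKO library held more than 2 and 81. Bst1 also differed between the genotypes at 0 h in a fit without both 0 h replicate 1 libraries (log2 −3.88, edgeR, BH-adjusted p = 0.0218). Putting the combined column in its place, and leaving out both 0 h replicate 1 libraries, were alternatives added after the data were seen. With the combined column, FNcKO 0 h replicate 1 was left out of its own group, so that its counts did not enter again.

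Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups as design, which left 14560 genes, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion and 4 group means was fitted to all 12 libraries. The TMM factors ran from 0.754 to 1.165. Differences were tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes of a comparison, and an adjusted p under 0.05 was called past the threshold. The 5 comparisons were 48 h against 0 h in WT, the same in FNcKO, FNcKO against WT at 48 h, FNcKO against WT at 0 h, and the difference of the 48 h responses between the genotypes. The genotype difference averaged over both times was added as a sixth after the data were seen. Levels are TMM-scaled counts per 1e6 (CPM), given as mean ± SD over 3 libraries unless said otherwise, and fold changes are those of the model. The SE beside a gene's log2 value is the size of that value divided by the square root of its F statistic. It is an approximation and not a standard error fitted by the model, so the SEs of separate comparisons need not combine. A count of 0 allows up to 3 counts, or 0.276 to 0.359 CPM depending on the library, for counting error only, and no fold is given against a group whose libraries all had 0 counts.

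Library totals ran from 8368160 to 10862573 counts. On counts simulated from these libraries' means and spread, the model recovered 27.3% of genes changed 2-fold and 78.0% of those changed 4-fold in the WT comparison over time, 38.4% and 73.0% in the FNcKO comparison over time, 23.0% and 68.0% between genotypes at 48 h, 28.3% and 75.0% at 0 h, and 5.00% and 51.5% for the difference of the responses. A gene that missed the threshold is therefore not shown to be unchanged. Each simulation changed 100 genes by each fold and left all others without a difference in the tested comparison. Far more genes passed in the real comparisons over time, so recovery there can differ. False calls were 9 of 114, 2 of 113, 3 of 94, 6 of 109 and 7 of 63 calls in the same order of comparisons. The biological coefficient of variation was 0.276. Replicates of every group differed by more than sampling noise, with chi-square values per degree of freedom between 18.6 and 110 for the 12 pairs of replicates, so no library was counted as a repeat of another.

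The groups, the comparisons, 26 gene lists with 460 entries, the rule for named genes and most of the other settings below were fixed before the data were examined. Bfsp2 is an entry of 2 lists. Of the list entries, 442 were in the files, 2 of them under another symbol. There were 15 lists for processes (fibrillar and matricellular matrix, basement membrane and lens capsule, smooth muscle type cytoskeleton, TGF-beta ligands, receptors and response, integrins, crystallins, other fiber cell genes, lens epithelial genes, cytokines, chemokines and acute phase, interferon response, immediate early genes, cell cycle, glycolysis and hypoxia, unfolded protein response, and proteases and inhibitors of the matrix). Another 8 held markers of other cells the dissection could bring along (neutrophils, macrophages and monocytes, general leukocytes, pigmented iris and ciliary cells, cornea, photoreceptors, vascular endothelium, erythroid cells), and 3 were checks (sex-linked genes, genes known to vary between the strains, and mitochondrial transcripts). No mitochondrial transcript was measured, which left 25 lists. Each was tested in each comparison by camera in limma 3.58.1 with a preset correlation between genes of 0.01, and p-values were adjusted over the 125 tests. A list counted as higher or lower when camera passed that threshold. Of the 125 tests, 67 passed with the preset correlation and 3 with an estimated one.

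The named genes are Fn1; up to 6 genes per direction and comparison with the largest fold change among those past the threshold with at least 10 CPM on average in a compared group, no overlap between the libraries of the compared groups (not asked of the difference of responses) and no predicted or clone name; up to 3 members of each list past the threshold with the largest fold change, or the member with the highest mean CPM where none passed; the sex-linked and strain check genes; and all members of a list with 5 or fewer past the threshold. Genes outside this rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

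Other settings fixed beforehand were the RLE size factors, total counts, TMM without fiber cell genes, no filter, a minimum of 5 CPM in 3 libraries, a fold change of at least 2, DESeq2 1.42.0, limma-voom with quality weights, the edgeR exact test, a fit of the compared groups only, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry, which tests whether a list moves one way on balance without comparing it with other genes. Added after the data were seen were the combined table column, leaving out both 0 h replicate 1 libraries, and fiber cell content or Xist level within a group as a covariate. The labels do not give the sex of the mice, and Xist ran from 4.96 to 3541 CPM across the libraries. The exact test and the fit of the compared groups only compare 2 groups, so they were not run for the difference of the responses or the averaged genotype difference. All others were run for every comparison. Gene lists were not tested with DESeq2, limma-voom, the exact test or the fit of the compared groups only. Some lists passed with fry and not with an estimated correlation, such as interferon response genes in WT over time (fry, BH-adjusted p = 0.00135). Others passed with neither, such as crystallins in WT over time (fry, BH-adjusted p = 0.0892).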

Results

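Gene expression was measured in lens epithelial cells on the lens capsule of mice directly after fiber cell removal and 48 h later, in wild type (WT) mice and in mice with a conditional knockout of fibronectin (FNcKO), 3 libraries per group. The stated aim of the series was to learn what fibronectin does in the scarring of the lens capsule that can follow cataract surgery. WT 0 h libraries held 10862573, 9400512 and 8734906 counts, WT 48 h libraries 9028674, 9257172 and 8814023, FNcKO 0 h libraries 9706747, 9246450 and 9251635, and FNcKO 48 h libraries 9177219, 9022930 and 8368160. Between 15924 and 16962 of the 24147 genes had a count in a library. The first principal component took 60.4% of the variance and separated 0 h from 48 h libraries, and the second took 11.3%.

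Fn1 encodes fibronectin, an extracellular matrix glycoprotein bound by integrins, and lies on chromosome 1 from 71585473 to 71653234 (mm10). Its level was 19.2 ± 3.76 CPM (SD, n = 3) in WT at 0 h and 1007 ± 494 at 48 h, with 1515, 528 and 979 CPM in the single libraries. In FNcKO it was 11.6 ± 4.51 CPM at 0 h and 377 ± 280 at 48 h, with 146, 298 and 688 CPM in the single libraries, so the 48 h libraries of the genotypes overlapped. Fn1 rose 52.4-fold in WT (log2 fold change 5.71, SE 0.63, edgeR, BH-adjusted p = 9.43e-05) and 32.2-fold in FNcKO (5.01, SE 0.61, edgeR, BH-adjusted p = 0.00029), where leaving out FNcKO 48 h replicate 3 gave a log2 fold change of 4.25. FNcKO against WT, Fn1 did not pass the threshold at 48 h (log2 −1.42, SE 0.52, edgeR, BH-adjusted p = 0.713) or at 0 h (−0.72, SE 0.54, 0.609), and neither did the difference of the responses (−0.70, 0.95). Over 26 alternatives the 48 h log2 difference ran from −2.19 to −0.999, and it passed the threshold only with fiber cell content as a covariate (−1.57, edgeR, BH-adjusted p = 0.0289). The labels do not say which exons were deleted, and whole-gene counts include reads outside a deleted part, so these levels neither check nor contradict the genotype labels.

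**Figure D1:**
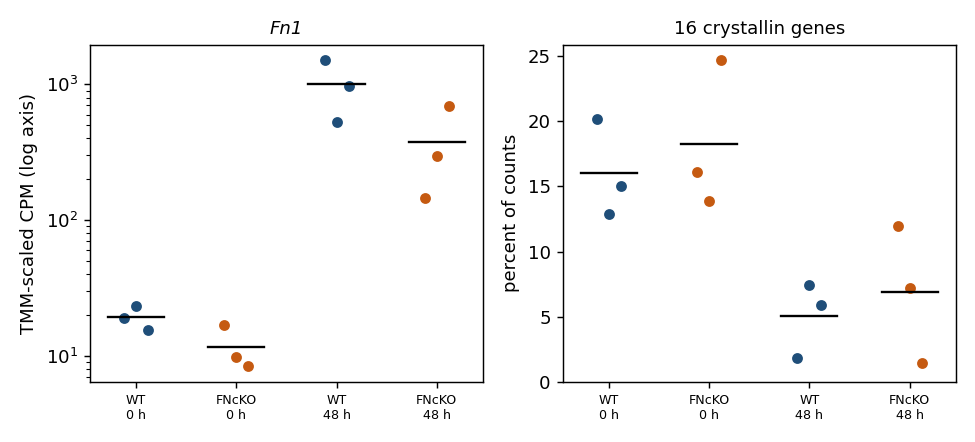
Fn1 level in TMM-scaled CPM on a log axis (left) and percent of all counts in 16 crystallin genes (right), each point a library and each line the mean of 3 libraries of WT or FNcKO at 0 h or 48 h. Fn1 was between 146 and 1515 CPM in every 48 h library, and the crystallin share ranged from 1.47% to 11.9% at 48 h and from 12.9% to 24.7% at 0 h.

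The comparison of 48 h with 0 h in WT asked how lens epithelial cells respond to fiber cell removal. Genes of the fibrillar and matricellular matrix and of the smooth muscle type cytoskeleton rose. Of 32 matrix genes, 20 rose and 3 fell (21 and 4 adjusted over the list alone). Tenascin C (Tnc), a matricellular protein of healing wounds, rose 116-fold from 8.47 ± 1.95 to 987 ± 575 CPM (log2 6.86, SE 0.59, edgeR, BH-adjusted p = 1.60e-05). Osteopontin (Spp1), a secreted integrin ligand, rose 125-fold from 5.36 ± 1.90 to 676 ± 206 CPM (6.97, SE 0.54, edgeR, BH-adjusted p = 9.16e-06). Of 16 genes of the smooth muscle type cytoskeleton, 14 rose and 0 fell (14 and 0 adjusted over the list alone). Transgelin (Tagln), an actin-binding protein of smooth muscle and myofibroblasts, rose 16.6-fold from 10.1 ± 3.85 to 169 ± 11.9 CPM (4.05, SE 0.24, edgeR, BH-adjusted p = 5.7e-07). Tagln2 rose 10.3-fold to 313 ± 88.3 CPM. The matrix list stood above other genes (camera, BH-adjusted p = 3.52e-11, adjusted p = 0.0389 with an estimated correlation). The cytoskeleton list did so as well (camera, BH-adjusted p = 2.72e-10, adjusted p = 0.126 with an estimated correlation).

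Of 30 genes for TGF-beta ligands, receptors and response, 12 rose and 3 fell in WT (13 and 3 adjusted over the list alone, camera, BH-adjusted p = 0.0105, adjusted p = 0.442 with an estimated correlation). Gremlin 1 (Grem1), a secreted BMP antagonist, rose 380.1-fold from 2.43 ± 0.626 to 920.1 ± 785 CPM (log2 8.57, SE 0.79, edgeR, BH-adjusted p = 3.85e-05), or 7.61 on the log2 scale without WT 48 h replicate 1. Of 18 integrin genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), and the list did not pass (camera, BH-adjusted p = 0.118). The laminin receptor chain Itga7 rose 31.4-fold from 8.99 ± 1.89 to 283 ± 92.1 CPM (4.97, SE 0.32, edgeR, BH-adjusted p = 8.75e-07). Itga5, a chain of the main fibronectin receptor, rose 7.21-fold from 26.9 ± 3.42 to 194 ± 61.1 CPM (2.85, SE 0.43, edgeR, BH-adjusted p = 0.000616). Basement membrane and capsule genes moved both ways, with 5 of 22 higher and 7 lower (5 and 9 adjusted over the list alone, camera, BH-adjusted p = 0.268). The laminin chain Lama3, chosen for WT after its values were seen, fell from 367 ± 75.3 to 77.4 ± 27.6 CPM (−2.25, SE 0.36, edgeR, BH-adjusted p = 0.000685).

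Inflammatory genes rose in WT. Of 32 cytokine, chemokine and acute phase genes, 31 rose and 0 fell (32 and 0 adjusted over the list alone, camera, BH-adjusted p = 2.10e-27, adjusted p = 0.0721 with an estimated correlation). The neutrophil chemokine Cxcl1, the acute phase protein Saa3 and the cytokine Il6 had 0 counts in every WT 0 h library and reached 16.5 ± 13.02, 5.07 ± 1.84 and 3.60 ± 1.36 CPM at 48 h (edgeR, BH-adjusted p = 0.000448, 0.00381 and 0.00362). Arginase 1 (Arg1), an enzyme of wound macrophages among other cells, rose 411-fold from 0.591 ± 0.338 to 242 ± 91.1 CPM (log2 8.68, SE 0.70, edgeR, BH-adjusted p = 1.58e-05). Of 22 interferon response genes 18 rose and 0 fell (20 and 0 adjusted over the list alone, camera, BH-adjusted p = 5.51e-09, adjusted p = 0.270 with an estimated correlation). The transcription factor Irf7 rose 8.32-fold from 4.65 ± 1.33 to 38.5 ± 12.4 CPM. Of 8 neutrophil markers 7 rose (8 adjusted over the list alone, camera, BH-adjusted p = 6.34e-05, adjusted p = 0.365 with an estimated correlation). Their summed level went from 8.94 ± 2.87 to 171 ± 169 CPM, with 365.7, 77.4 and 68.6 CPM in the single 48 h libraries. Of 15 macrophage and monocyte markers 8 rose (10 adjusted over the list alone, camera, BH-adjusted p = 3.24e-05, adjusted p = 0.442 with an estimated correlation). Their summed level went from 145 ± 55.8 to 595 ± 302 CPM. The chemokine receptor Ccr2 of inflammatory monocytes rose from 0.396 ± 0.0880 to 35.4 ± 21.8 CPM (6.45, SE 0.66, edgeR, BH-adjusted p = 3.77e-05), or 5.84 on the log2 scale without WT 48 h replicate 1. All 4 general leukocyte markers rose (4 adjusted over the list alone, camera, BH-adjusted p = 0.00122, adjusted p = 0.365 with an estimated correlation). Coro1a, an actin regulator of leukocytes, rose 16.6-fold to 20.4 ± 9.35 CPM.

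Proliferation, early response and stress genes rose in the same WT comparison. Of 30 cell cycle genes 28 rose and 0 fell (29 and 0 adjusted over the list alone, camera, BH-adjusted p = 4.78e-20, adjusted p = 0.342 with an estimated correlation). The mitotic kinases Aurkb and Plk1 rose 20.3-fold to 27.9 ± 12.4 CPM (log2 4.35, SE 0.57, edgeR, BH-adjusted p = 0.00022) and 15.96-fold to 39.7 ± 24.0 CPM (SE of the log2 value 0.58, edgeR, BH-adjusted p = 0.000504). Of 20 immediate early genes 14 rose and 0 fell (14 and 0 adjusted over the list alone, camera, BH-adjusted p = 2.47e-12, adjusted p = 0.0801 with an estimated correlation). The transcription factor Egr1 rose 16.01-fold from 12.8 ± 5.29 to 205 ± 36.7 CPM (SE of the log2 value 0.27, edgeR, BH-adjusted p = 1.29e-06). Of 16 unfolded protein response genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera, BH-adjusted p = 2.95e-06, adjusted p = 0.270 with an estimated correlation). Asparagine synthetase (Asns) rose 4.67-fold to 24.4 ± 4.88 CPM. Of 20 matrix proteases and inhibitors 11 rose and 1 fell (12 and 3 adjusted over the list alone, camera, BH-adjusted p = 5.44e-07, adjusted p = 0.129 with an estimated correlation). The urokinase receptor Plaur rose from 0.275 ± 0.200 to 58.5 ± 22.3 CPM (7.62, SE 0.82, edgeR, BH-adjusted p = 8.58e-05), or 8.35 on the log2 scale without WT 0 h replicate 1. Glycolysis and hypoxia genes went both ways, 2 higher and 2 lower of 21 (1 and 2 adjusted over the list alone, camera, BH-adjusted p = 0.856). The glucose transporter Slc2a1 fell from 1177 ± 205 to 671 ± 55.9 CPM (−0.81, SE 0.22, edgeR, BH-adjusted p = 0.0128), a call lost without WT 0 h replicate 3 (0.0602) or WT 48 h replicate 1 (0.0541).

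The share of counts in 16 crystallin genes, the main soluble proteins of the lens, was 16.03% ± 3.75 at 0 h in WT and 5.05% ± 2.92 at 48 h. Of the 16 genes 5 fell (12 adjusted over the list alone, camera, BH-adjusted p = 0.000283, adjusted p = 0.527 with an estimated correlation). Cryab, a small heat shock protein of lens and muscle, fell from 25180 ± 6870 to 6399 ± 3550 CPM (log2 −1.98, SE 0.68, edgeR, BH-adjusted p = 0.0402). This call was lost without any 1 of the WT libraries (0.053 to 0.12), without FNcKO 0 h replicate 1 (0.0536) and without FNcKO 48 h replicate 2 (0.0507). Of 19 other fiber cell genes 10 fell and 0 rose (16 and 0 adjusted over the list alone, camera, BH-adjusted p = 1.26e-05, adjusted p = 0.447 with an estimated correlation). The beaded filament protein Bfsp1 fell from 503 ± 254 to 71.7 ± 71.9 CPM (−2.81, SE 0.74, edgeR, BH-adjusted p = 0.0152), or by 4.04 on the log2 scale without WT 48 h replicate 2. Its call was lost without WT 48 h replicate 3 (0.0533). Of 16 lens epithelial genes 3 rose and 5 fell (3 and 5 adjusted over the list alone). The matrix protein Npnt fell 7.76-fold from 376 ± 143 to 48.5 ± 20.9 CPM (−2.96, SE 0.45, edgeR, BH-adjusted p = 0.000598). The receptor Fgfr3 fell 4.48-fold to 69.1 ± 28.7 CPM. The Notch ligand Jag1 rose 2.88-fold to 482 ± 205 CPM. The epithelial list did not pass (camera, BH-adjusted p = 0.0566), but did without WT 0 h replicate 1 (0.0486), WT 0 h replicate 2 (0.0225) or FNcKO 48 h replicate 3 (0.0156). Outside the lists the matrix glycoprotein gene Emilin3 fell 27.2-fold from 59.8 ± 19.5 to 2.20 ± 1.25 CPM (−4.77, SE 0.70, edgeR, BH-adjusted p = 0.000589).

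Markers of other eye cells moved in different directions in WT. Of 9 pigment cell markers 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera, BH-adjusted p = 0.657). Slc24a5, a cation exchanger of melanosomes, rose 4.22-fold to 15.3 ± 7.60 CPM. Oca2, a melanosomal channel protein, fell 10.5-fold from 81.8 ± 21.8 to 7.73 ± 3.88 CPM (log2 −3.40, SE 0.41, edgeR, BH-adjusted p = 0.000125). Of 10 vascular endothelial markers 5 rose (5 adjusted over the list alone, camera, BH-adjusted p = 0.0224, adjusted p = 0.561 with an estimated correlation, and 0.0919 with camera without WT 48 h replicate 2). Corneal markers had 2 of 7 lower (2 adjusted over the list alone, camera, BH-adjusted p = 0.313). The keratin Krt4 fell 13.8-fold to 0.434 ± 0.294 CPM. Photoreceptor markers had 2 of 14 lower (0 adjusted over the list alone, camera, BH-adjusted p = 0.067). The photoreceptor list passed without WT 0 h replicate 3 (0.00663), WT 48 h replicate 2 (0.018), FNcKO 0 h replicate 2 (0.0498) or FNcKO 48 h replicate 2 (0.022). None of 2 erythroid, 5 sex-linked and 4 strain check genes passed in edgeR, though 2 of the strain check genes were lower adjusted over the list alone.

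In total 4745 of 14560 genes passed in WT (edgeR's quasi-likelihood test, BH-adjusted p under 0.05), 2775 higher and 1970 lower, and 2976 of them changed at least 2-fold. The libraries of the 2 times did not overlap for 4649 of these genes, and for 51.5% of all tested genes, where chance gives 10%. With total counts as the scale 76.2% rather than 58.5% of the calls were higher, with the median log2 change of all genes at 0.23.

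The same comparison in FNcKO asked how cells of the knockout respond. Matrix and contractile genes rose here too. Of 32 matrix genes 15 rose and 2 fell (15 and 3 adjusted over the list alone, camera, BH-adjusted p = 3.27e-07, adjusted p = 0.0721 with an estimated correlation). Tnc rose 115.5-fold from 8.34 ± 0.534 to 964 ± 470.0 CPM (log2 6.85, SE 0.59, edgeR, BH-adjusted p = 2.05e-05). Tgfbi, a secreted matrix protein induced by TGF-beta, rose 35.3-fold from 21.5 ± 6.20 to 763 ± 206 CPM (5.14, SE 0.37, edgeR, BH-adjusted p = 2.40e-06). Spp1 rose from 3.26 ± 1.11 to 329 ± 202 CPM (6.64, SE 0.54, edgeR, BH-adjusted p = 1.49e-05), or 6.05 on the log2 scale without FNcKO 48 h replicate 3. Of 16 smooth muscle type genes 9 rose and 0 fell (11 and 0 adjusted over the list alone, camera, BH-adjusted p = 2.00e-07, adjusted p = 0.196 with an estimated correlation). Tagln rose 7.96-fold to 70.0 ± 9.62 CPM, Tagln2 9.32-fold to 324 ± 108 CPM and the calponin Cnn2 4.31-fold to 100.1 ± 31.4 CPM. Of 30 TGF-beta genes 12 rose and 2 fell (13 and 2 adjusted over the list alone, camera, BH-adjusted p = 0.0109, adjusted p = 0.442 with an estimated correlation, and 0.116 with camera without FNcKO 0 h replicate 3). Grem1 rose 49.9-fold to 132 ± 76.7 CPM (5.64, SE 0.72, edgeR, BH-adjusted p = 0.000388). Of 18 integrin genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera, BH-adjusted p = 0.0354, adjusted p = 0.358 with an estimated correlation, and with camera 0.121 without FNcKO 0 h replicate 3 and 0.0594 without FNcKO 48 h replicate 2). Itga7 rose 28.4-fold, Itga5 7.84-fold and Itgb4, a chain of hemidesmosomes, 3.20-fold. Of 22 basement membrane genes 4 rose and 3 fell (5 and 6 adjusted over the list alone, camera, BH-adjusted p = 0.447). Lama3 fell by 1.72 on the log2 scale.

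Inflammatory and immune cell genes rose in FNcKO as well. Of 32 cytokine and acute phase genes 30 rose and 0 fell (31 and 0 adjusted over the list alone, camera, BH-adjusted p = 1.59e-31, adjusted p = 0.0721 with an estimated correlation). Saa3 and Il6 had 0 counts in every FNcKO 0 h library and 4.10 ± 4.96 and 2.64 ± 2.27 CPM at 48 h (edgeR, BH-adjusted p = 0.00707 and 0.00782). The lipoxygenase gene Alox15 rose 175-fold from 0.381 ± 0.178 to 66.7 ± 29.5 CPM (log2 7.45, SE 0.54, edgeR, BH-adjusted p = 4.13e-06). Of 22 interferon response genes 18 rose and 0 fell (20 and 0 adjusted over the list alone, camera, BH-adjusted p = 3.25e-12, adjusted p = 0.160 with an estimated correlation). The guanylate-binding protein Gbp3 rose 18.9-fold to 15.3 ± 0.311 CPM (4.24, SE 0.51, edgeR, BH-adjusted p = 0.000122). Neutrophil markers had 6 of 8 higher (8 adjusted over the list alone, camera, BH-adjusted p = 3.24e-05, adjusted p = 0.365 with an estimated correlation). Their sum went from 4.64 ± 0.650 to 75.1 ± 44.5 CPM, with 50.4, 48.4 and 126 CPM in the single 48 h libraries. Macrophage and monocyte markers had 8 of 15 higher and 1 lower (8 and 1 adjusted over the list alone, camera, BH-adjusted p = 0.000849, adjusted p = 0.517 with an estimated correlation). Their sum went from 109 ± 35.7 to 356 ± 143 CPM. Cd14, a receptor of monocytes for bacterial lipopolysaccharide, rose 13.6-fold to 33.3 ± 9.91 CPM (3.76, SE 0.59, edgeR, BH-adjusted p = 0.00103). General leukocyte markers had 3 of 4 higher (4 adjusted over the list alone, camera, BH-adjusted p = 0.0017, adjusted p = 0.365 with an estimated correlation).

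Cell cycle genes rose in FNcKO, 29 of 30 (29 adjusted over the list alone, camera, BH-adjusted p = 3.99e-23, adjusted p = 0.270 with an estimated correlation). The topoisomerase Top2a rose 11.2-fold to 276 ± 93.3 CPM (log2 3.48, SE 0.62, edgeR, BH-adjusted p = 0.00263). Of 20 immediate early genes 14 rose and 1 fell (14 and 2 adjusted over the list alone, camera, BH-adjusted p = 1.85e-09, adjusted p = 0.126 with an estimated correlation). The transcription factor Junb rose 16.7-fold from 5.34 ± 0.777 to 89.6 ± 23.6 CPM (4.06, SE 0.31, edgeR, BH-adjusted p = 4.13e-06). Of 16 unfolded protein response genes 8 rose and 1 fell (10 and 1 adjusted over the list alone, camera, BH-adjusted p = 0.00554, adjusted p = 0.442 with an estimated correlation). Xbp1, a transcription factor of this response, rose 1.83-fold from 70.7 ± 8.39 to 130 ± 19.4 CPM. Of 20 matrix proteases and inhibitors 11 rose and 1 fell (12 and 4 adjusted over the list alone, camera, BH-adjusted p = 1.52e-06, adjusted p = 0.153 with an estimated correlation). Urokinase (Plau) rose 35.7-fold from 1.86 ± 0.776 to 65.4 ± 44.5 CPM (5.16, SE 0.78, edgeR, BH-adjusted p = 0.00103). Of 21 glycolysis and hypoxia genes 2 rose and 5 fell (2 and 6 adjusted over the list alone, camera, BH-adjusted p = 0.00707, adjusted p = 0.365 with an estimated correlation). Slc2a1 fell 2.25-fold from 1436 ± 219 to 637 ± 130 CPM (−1.17, SE 0.22, edgeR, BH-adjusted p = 0.00211). The mitophagy receptor Bnip3, a hypoxia target, fell 2.84-fold from 86.8 ± 9.04 to 30.5 ± 11.1 CPM (−1.51, SE 0.23, edgeR, BH-adjusted p = 0.000557).

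In FNcKO the crystallin share was 18.2% ± 5.74 at 0 h and 6.87% ± 5.23 at 48 h, with 11.9%, 7.22% and 1.47% in the single 48 h libraries. Of 16 crystallin genes 4 fell (14 adjusted over the list alone, camera, BH-adjusted p = 3.24e-05, adjusted p = 0.442 with an estimated correlation). The gamma crystallin Crygb went from 516 ± 507 to 14.7 ± 14.4 CPM (log2 −5.13, SE 1.55, edgeR, BH-adjusted p = 0.0343). Its log2 value was −3.98 without FNcKO 0 h replicate 3 and −6.29 without FNcKO 48 h replicate 1. The Crygb call was lost without FNcKO 0 h replicate 3 (0.0863), FNcKO 48 h replicate 2 (0.0792) or FNcKO 48 h replicate 3 (0.134). Of 19 other fiber cell genes 10 fell and 0 rose (13 and 0 adjusted over the list alone, camera, BH-adjusted p = 7.63e-07, adjusted p = 0.442 with an estimated correlation). The fiber cell nuclease Dnase2b fell from 3.28 ± 1.67 to 0.250 ± 0.125 CPM (−3.64, SE 0.91, edgeR, BH-adjusted p = 0.0108). Of 16 lens epithelial genes 3 rose and 9 fell (3 and 11 adjusted over the list alone, camera, BH-adjusted p = 0.000849, adjusted p = 0.270 with an estimated correlation). Npnt fell 7.86-fold from 564 ± 121 to 71.8 ± 35.4 CPM (−2.97, SE 0.45, edgeR, BH-adjusted p = 0.000816), while Jag1 rose 3.65-fold. Outside the lists R3hdml fell from 2701 ± 1690 to 67.3 ± 66.4 CPM (−5.33, SE 0.92, edgeR, BH-adjusted p = 0.00227), or by 4.71 on the log2 scale without FNcKO 0 h replicate 3 and 6.50 without FNcKO 48 h replicate 1. Pigment cell markers had 3 of 9 lower and 0 higher (3 and 0 adjusted over the list alone, camera, BH-adjusted p = 0.00354, adjusted p = 0.442 with an estimated correlation). Oca2 fell 12.5-fold to 5.68 ± 2.41 CPM (−3.64, SE 0.42, edgeR, BH-adjusted p = 0.000148). Corneal markers had 3 of 7 lower (5 adjusted over the list alone, camera, BH-adjusted p = 0.0138, adjusted p = 0.365 with an estimated correlation, and 0.057 with camera without FNcKO 0 h replicate 3). Vascular markers had 7 of 10 higher (7 adjusted over the list alone, camera, BH-adjusted p = 0.00238, adjusted p = 0.442 with an estimated correlation). None of 14 photoreceptor markers passed in edgeR (camera, BH-adjusted p = 0.316), nor did any of 2 erythroid or 5 sex-linked genes. Of 4 strain check genes Nnt and Bfsp2 were lower (2 adjusted over the list alone). Nnt, a mitochondrial transhydrogenase, fell from 111 ± 8.09 to 68.3 ± 13.1 CPM (edgeR, BH-adjusted p = 0.00799, and 0.0845 with total counts as the scale).

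In total 3611 genes passed in FNcKO (edgeR's quasi-likelihood test, BH-adjusted p under 0.05), 2169 higher and 1442 lower, 2322 of them at least 2-fold. Their libraries did not overlap for 3448 of the genes, and for 37.5% of all tested genes against 10% by chance. Without FNcKO 48 h replicate 3, 2232 genes passed, and without both 0 h replicate 1 libraries 2299 passed. With total counts as the scale 82.4% rather than 60.1% of the calls were higher, with the median log2 change of all genes at 0.29.

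The responses of the genotypes, which share no library, were alike across genes, with a Pearson r of 0.859 and a Spearman rho of 0.789 over 14560 genes that are not independent replicates. Of the 4745 genes called in WT, 4630 had the same sign in FNcKO, and of the 3611 called in FNcKO, 3571 had the same sign in WT. Both responses called 1837 genes higher and 1003 lower, where independent lists would share 413 and 195. The insulin-like growth factor binding protein gene Igfbp2, chosen after its values were seen, was called in opposite directions, higher in WT at 48 h and lower in FNcKO. Its means in WT and FNcKO were 19.3 and 123 CPM at 0 h and 51.3 and 69.0 CPM at 48 h. The difference of its responses did not pass in the main fit (log2 −2.25, edgeR, BH-adjusted p = 0.284). It passed with DESeq2 (BH-adjusted p = 0.000544) and in edgeR with fiber cell content as a covariate (BH-adjusted p = 0.0051).

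**Figure D2:**
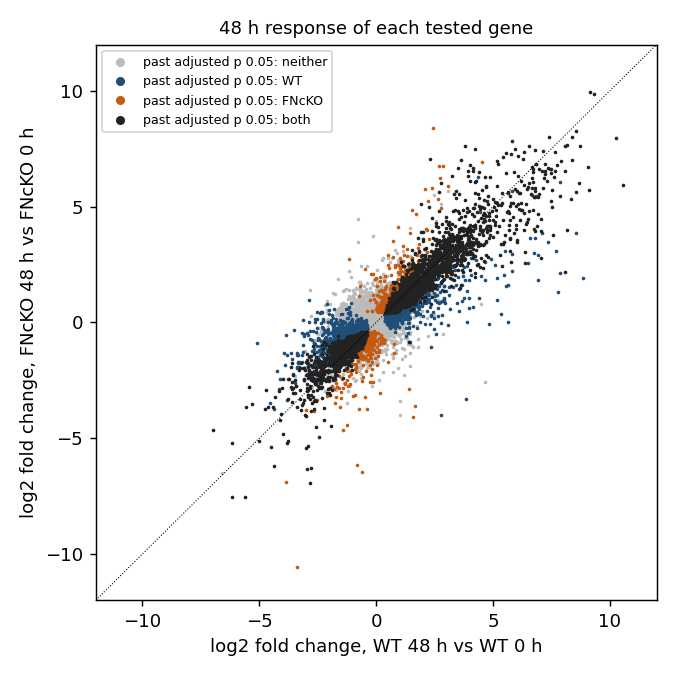
Log2 fold change at 48 h against 0 h in WT (horizontal axis) and FNcKO (vertical axis), each point a tested gene, coloured by whether edgeR's BH-adjusted p was under 0.05 in neither, WT, FNcKO or both, with equal responses on the dotted diagonal. Most of the 14560 genes lie along the diagonal, with r = 0.859.

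**Figure D3:**
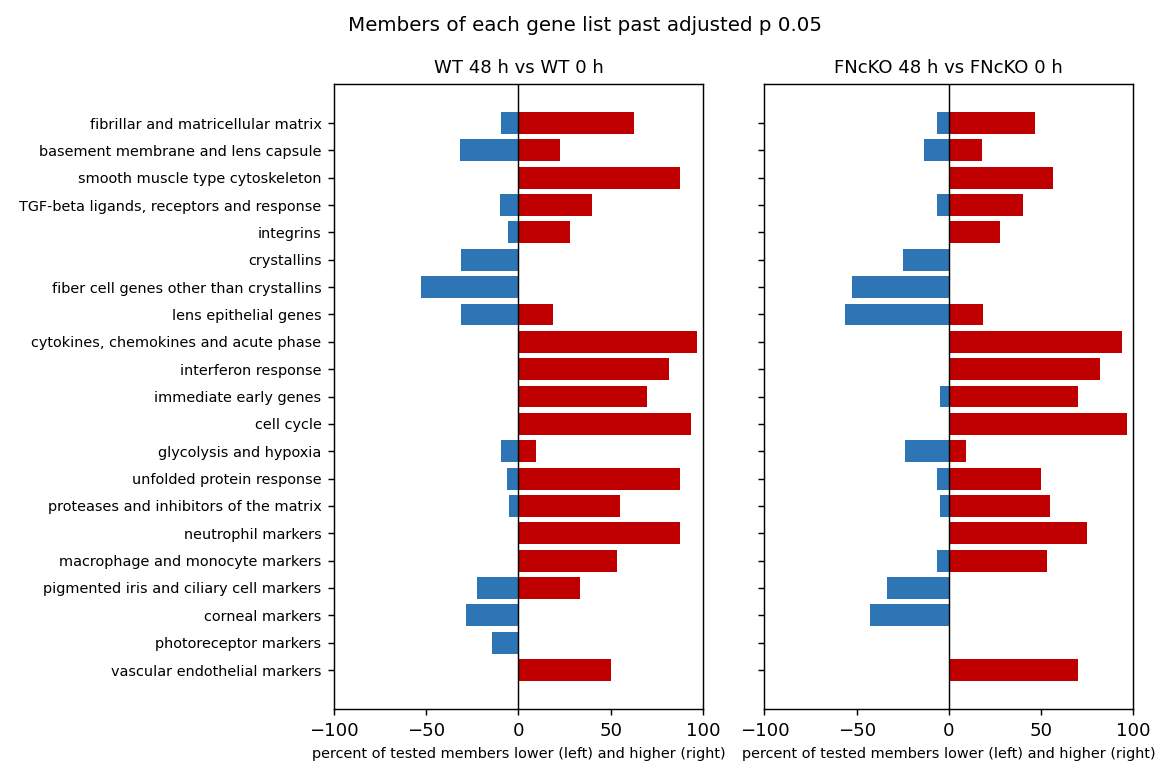
Percent of the tested members of 21 gene lists that were higher or lower at 48 h than at 0 h (edgeR, BH-adjusted p under 0.05) in WT and in FNcKO. Cytokine and cell cycle genes were higher with 31 of 32 and 28 of 30 members in WT, and other fiber cell genes were lower with 10 of 19 members in each genotype.

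The comparison of the genotypes at 48 h asked what differed in FNcKO cells after fiber cell removal. Of 32 matrix genes 3 were lower in FNcKO and 0 higher (6 and 0 adjusted over the list alone), namely the collagen crosslinking enzyme Lox, the collagen chain Col1a1 and periostin (Postn). Lox was 4.56-fold lower, at 23.4 ± 9.49 against 107 ± 20.2 CPM (log2 −2.19, SE 0.28, edgeR, BH-adjusted p = 0.00375). Col1a1 was 6.49-fold lower, at 50.6 ± 5.74 against 329 ± 175 CPM (−2.70, SE 0.41, edgeR, BH-adjusted p = 0.0265). Postn was 4.58-fold lower, at 12.3 ± 3.997 against 56.5 ± 11.7 CPM (−2.20, SE 0.40, edgeR, BH-adjusted p = 0.048). Of 16 smooth muscle type genes Tagln was lower, at 70.0 ± 9.62 against 169 ± 11.9 CPM (−1.27, SE 0.21, edgeR, BH-adjusted p = 0.0296), with 3 lower adjusted over the list alone. In the same libraries the summed level of 9 pigment cell markers was 44.9 ± 25.9 against 352.5 ± 151 CPM. The matrix list stood below other genes (camera, BH-adjusted p = 1.86e-10, adjusted p = 0.0389 with an estimated correlation). The smooth muscle list did so with the preset correlation (camera, BH-adjusted p = 0.000918, adjusted p = 0.365 with an estimated correlation). Its call was lost without WT 48 h replicate 3 (0.222) or FNcKO 48 h replicate 1 (0.384). No Lox call was lost by leaving out 1 library, and it was lost in a fit of the 48 h groups alone (edgeR, BH-adjusted p = 0.145). Col1a1 lost its call without FNcKO 0 h replicate 3 (0.0646) or FNcKO 48 h replicates 1, 2 or 3 (0.0998, 0.133 and 0.0785). Postn lost it without any 1 library other than WT 0 h replicates 1 and 3 (0.066 to 0.178). Tagln lost it without any 1 of the WT 48 h libraries, FNcKO 0 h replicates 1 or 2 or FNcKO 48 h replicates 1 or 2 (0.0528 to 0.207).

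In the Serpina3 cluster of serine protease inhibitors on chromosome 12, 4 genes were lower in FNcKO at 48 h. Serpina3f was at 0.250 ± 0.222 CPM in FNcKO and 41.2 ± 13.2 in WT (log2 −7.29, SE 0.66, edgeR, BH-adjusted p = 0.000141). Serpina3m was at 0.496 ± 0.320 and 48.1 ± 13.02 (−6.56, SE 0.44, edgeR, BH-adjusted p = 1.48e-05). Serpina3c was at 0.322 ± 0.187 and 19.97 ± 7.51 (−5.90, SE 0.53, edgeR, BH-adjusted p = 0.000141), and Serpina3h at 2.82 ± 1.25 and 38.6 ± 6.33 (−3.77, SE 0.38, edgeR, BH-adjusted p = 0.000342). None of these 4 calls was lost without any 1 library, though the log2 value became −7.88 for Serpina3f without FNcKO 48 h replicate 1 and −7.17 for Serpina3m without FNcKO 48 h replicate 3. These genes are close paralogs, and how shared reads were counted is not given in the sources used here. Complement C2 was 13.3-fold lower, at 1.42 ± 0.695 against 19.01 ± 7.11 CPM (−3.73, SE 0.43, edgeR, BH-adjusted p = 0.00129). The C2 call was kept without any 1 library and lost in a fit of the 48 h groups alone (edgeR, BH-adjusted p = 0.0752).

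Of 9 pigment cell markers 3 were lower in FNcKO at 48 h and 0 higher (7 and 0 adjusted over the list alone, camera, BH-adjusted p = 3.61e-24, adjusted p = 0.0389 with an estimated correlation). The melanin synthesis enzyme Tyrp1 was at 18.1 ± 10.9 against 122 ± 43.7 CPM (log2 −2.75, SE 0.43, edgeR, BH-adjusted p = 0.0292). Tyrosinase (Tyr) was at 2.74 ± 2.25 against 32.6 ± 24.5 (−3.57, SE 0.62, edgeR, BH-adjusted p = 0.0442), and the melanosome protein Mlana was at 1.03 ± 0.253 against 17.7 ± 9.98 (−4.09, SE 0.66, edgeR, BH-adjusted p = 0.0271). Tyrp1 lost its call without WT 48 h replicates 1 or 2, any 1 FNcKO 0 h library or FNcKO 48 h replicate 2 (0.0528 to 0.139). Mlana lost it without WT 48 h replicates 1 or 2, FNcKO 0 h replicate 1 or any 1 FNcKO 48 h library (0.0568 to 0.175). Tyr lost it without any 1 library other than WT 0 h replicate 3, WT 48 h replicate 3 and FNcKO 48 h replicate 1 (0.0616 to 0.236). Its log2 value was −2.75 without WT 48 h replicate 1 and −4.42 without FNcKO 48 h replicate 1. The summed level of the 9 markers was 352.5 ± 151 CPM in WT and 44.9 ± 25.9 in FNcKO.

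Immune gene lists stood below other genes in FNcKO at 48 h with the preset correlation and not with an estimated one. This held for macrophage markers (0 of 15 past, 3 lower adjusted over the list alone, camera, BH-adjusted p = 5.44e-07, adjusted p = 0.365 with an estimated correlation). It also held for interferon response genes (0 of 22 past, 1 lower adjusted over the list alone, camera, BH-adjusted p = 0.000183, adjusted p = 0.410 with an estimated correlation). The same was seen for glycolysis and hypoxia genes (camera, BH-adjusted p = 0.00234, adjusted p = 0.297 with an estimated correlation). Interferon response genes stood lower already at 0 h, with a median log2 difference of −0.60, against −0.39 at 48 h. Their difference of the responses did not pass (camera, BH-adjusted p = 0.17). The most abundant macrophage marker, the lysozyme Lyz2, was at 98.1 ± 38.4 against 118 ± 48.3 CPM and did not pass (edgeR, BH-adjusted p = 1.0). The acute phase gene Lcn2, at 3784 ± 2090 against 5087 ± 1110 CPM, did not pass either (edgeR, BH-adjusted p = 1.0). Further lists passed at 48 h with 0 members past the threshold and with calls that depended on single libraries. Cell cycle genes stood higher (camera, BH-adjusted p = 9.79e-05, adjusted p = 0.623 with an estimated correlation), lost without FNcKO 48 h replicate 3 (0.233) and of the other sign without WT 48 h replicate 2 (0.679). Unfolded protein response genes stood lower (camera, BH-adjusted p = 0.0071, adjusted p = 0.442 with an estimated correlation), lost without WT 48 h replicate 2 (0.0983) or FNcKO 48 h replicate 1 (0.154). General leukocyte markers stood lower (camera, BH-adjusted p = 0.00531, adjusted p = 0.399 with an estimated correlation), lost without WT 48 h replicate 1 (0.198) or FNcKO 48 h replicate 1 (0.224). Vascular markers stood lower (camera, BH-adjusted p = 0.0143, adjusted p = 0.527 with an estimated correlation), lost without WT 48 h replicate 2 (0.613) or FNcKO 48 h replicates 1 or 2 (0.17 and 0.143). Neutrophil markers stood lower (camera, BH-adjusted p = 0.0193, adjusted p = 0.527 with an estimated correlation), lost without WT 48 h replicate 1 (0.955) or FNcKO 48 h replicates 1 or 2 (0.253 and 0.112). Basement membrane genes stood higher (camera, BH-adjusted p = 0.0398, adjusted p = 0.660 with an estimated correlation), lost without WT 48 h replicates 1 or 2 (0.202 and 0.28) or FNcKO 48 h replicates 1 or 2 (0.373 and 0.503). Cytokine genes stood lower (camera, BH-adjusted p = 0.0469, adjusted p = 0.684 with an estimated correlation), of the other sign without WT 48 h replicate 1 (0.712) and lost without WT 0 h replicate 2 (0.0555), WT 48 h replicate 2 (0.0532), FNcKO 0 h replicate 3 (0.0553) or FNcKO 48 h replicates 1 or 2 (0.902 and 0.144). TGF-beta, integrin, crystallin, fiber cell, lens epithelial, immediate early, protease, corneal and photoreceptor lists did not pass at 48 h. Of 4 genes known to vary between the strains 0 passed in edgeR at 48 h (0 with an unadjusted p under 0.05), with log2 values from −0.25 to 0.20 (camera, BH-adjusted p = 0.684).

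Genes higher in FNcKO at 48 h were few. The secreted glutathione peroxidase Gpx3 was at 697 ± 194 against 239 ± 59.1 CPM (log2 1.55, SE 0.29, edgeR, BH-adjusted p = 0.0498). The endothelin-converting enzyme Ece1 was at 443 ± 134 against 188 ± 17.3 (1.24, SE 0.23, edgeR, BH-adjusted p = 0.0487), and the junction protein Jam2 at 76.1 ± 18.98 against 32.9 ± 0.567 (1.21, SE 0.22, edgeR, BH-adjusted p = 0.0442). Gpx3 and Ece1 lost their calls without any 1 library other than FNcKO 48 h replicate 3 (0.0508 to 0.241 and 0.0638 to 0.236). Jam2 lost its call without any 1 other than WT 0 h replicate 2 and FNcKO 48 h replicate 3 (0.0544 to 0.182).

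In total 35 genes passed between the genotypes at 48 h (edgeR's quasi-likelihood test, BH-adjusted p under 0.05), 6 higher and 29 lower in FNcKO, while 796 had an unadjusted p under 0.05 where chance gives 728. The libraries did not overlap for any of the 35 genes, and for 9.74% of all tested genes against 10% by chance. DESeq2 called 119 genes, limma-voom 28, the edgeR exact test 110 and a fit of the 48 h groups alone 7. Leaving out 1 library gave 23 genes (WT 0 h replicate 1), 14 (WT 48 h replicate 1), 14 (WT 48 h replicate 2), 17, 19 and 22 (FNcKO 0 h replicates 1, 2 and 3). It gave 16, 10 and 21 genes without FNcKO 48 h replicates 1, 2 and 3, and between 27 and 46 for the other libraries.

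The comparison of the genotypes at 0 h gives the differences present directly after fiber cell removal. Bst1, a membrane ectoenzyme of NAD metabolism, was 15.5-fold lower in FNcKO, at 9.25 ± 2.06 against 143 ± 37.8 CPM (log2 −3.95, SE 0.30, edgeR, BH-adjusted p = 6.89e-05), a call kept without any 1 library. Igfbp2 was 6.38-fold higher, at 123 ± 28.6 against 19.3 ± 1.99 CPM (2.67, SE 0.30, edgeR, BH-adjusted p = 0.00259, and 0.0596 without WT 0 h replicate 2). It lies on chromosome 1 from 72824480 to 72852471, near Fn1. The water channel Aqp1, a lens epithelial gene, was 2.53-fold higher, at 1341 ± 260 against 530 ± 67.3 CPM (1.34, SE 0.21, edgeR, BH-adjusted p = 0.0283). The complement genes C4b and C3 were lower, C4b 6.34-fold at 48.2 ± 23.6 against 306 ± 84.3 CPM (−2.66, SE 0.38, edgeR, BH-adjusted p = 0.0283) and C3 3.78-fold at 23.3 ± 6.57 against 88.3 ± 37.0 CPM (−1.92, SE 0.33, edgeR, BH-adjusted p = 0.0397). The death ligand Tnfsf10 was 3.06-fold lower, at 10.6 ± 2.38 against 32.7 ± 4.85 CPM (−1.62, SE 0.25, edgeR, BH-adjusted p = 0.0283). Aqp1 and Tnfsf10 lost their calls without any 1 of the 0 h libraries or FNcKO 48 h replicate 2 (0.055 to 0.233 and 0.0543 to 0.177). C4b lost it without WT 0 h replicates 2 or 3, FNcKO 0 h replicates 1 or 2 or FNcKO 48 h replicate 2 (0.052 to 0.16). C3 lost it without WT 0 h replicates 2 or 3, WT 48 h replicate 3, any 1 FNcKO 0 h library or FNcKO 48 h replicate 2 (0.0554 to 0.242).

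Matrix genes did not differ at 0 h as a list (camera, BH-adjusted p = 0.875), with 0 of 32 past the threshold (3 higher and 1 lower adjusted over the list alone). The most abundant, Sparc, was at 5971 ± 846 CPM in FNcKO and 4377 ± 1340 in WT. Smooth muscle type genes (camera, BH-adjusted p = 0.42), TGF-beta genes (0.767) and pigment cell markers (0.102) did not pass, though the pigment list did without WT 0 h replicate 3 (0.028). Interferon response genes stood lower in FNcKO (0 of 22 past, 4 lower adjusted over the list alone, camera, BH-adjusted p = 1.20e-05, adjusted p = 0.365 with an estimated correlation). So did photoreceptor markers (0 of 14 past, camera, BH-adjusted p = 0.000843, adjusted p = 0.571 with an estimated correlation) and vascular markers (0 of 10 past, camera, BH-adjusted p = 0.00252, adjusted p = 0.442 with an estimated correlation). Cell cycle genes stood higher (0 of 30 past, camera, BH-adjusted p = 3.24e-05, adjusted p = 0.582 with an estimated correlation). The photoreceptor markers, which the lens does not make in quantity, summed to 2360 ± 1723 CPM in FNcKO (1526, 4341 and 1213 in the single libraries) and 4416 ± 2392 in WT at 0 h. Of 4 genes known to vary between the strains 0 passed in edgeR at 0 h (0 with an unadjusted p under 0.05), with log2 values from −0.30 to 0.47 (camera, BH-adjusted p = 0.856). Lens epithelial genes stood higher (camera, BH-adjusted p = 0.0224, adjusted p = 0.442 with an estimated correlation), lost without WT 0 h replicate 1 (0.0761) or FNcKO 0 h replicate 2 (0.0505). Immediate early genes stood higher (camera, BH-adjusted p = 0.0134, adjusted p = 0.442 with an estimated correlation), lost without WT 0 h replicate 3 (0.154) or FNcKO 0 h replicate 1 (0.0626). Corneal markers stood higher (camera, BH-adjusted p = 0.0143, adjusted p = 0.365 with an estimated correlation), lost without FNcKO 0 h replicate 1 (0.0577). Glycolysis genes stood higher (camera, BH-adjusted p = 0.0153, adjusted p = 0.371 with an estimated correlation), lost without WT 0 h replicate 1 (0.0734). Unfolded protein response genes stood higher (camera, BH-adjusted p = 0.0264, adjusted p = 0.527 with an estimated correlation), lost without WT 0 h replicate 1 (0.156) or FNcKO 0 h replicates 2 or 3 (0.0727 and 0.17).

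In total 21 genes passed at 0 h (edgeR's quasi-likelihood test, BH-adjusted p under 0.05), 11 higher and 10 lower in FNcKO, all at least 2-fold and without overlap of their libraries. Some 16.6% of all tested genes had no overlap, against 10% by chance, and 1603 had an unadjusted p under 0.05 against 728 by chance. DESeq2 called 129 genes, limma-voom 18 and the edgeR exact test 206. Without WT 0 h replicates 1, 2 or 3 the count was 7, 2 and 4, without FNcKO 0 h replicates 1, 2 or 3 it was 4, 4 and 9, and without FNcKO 48 h replicate 2 it was 5. With the combined table column in place of WT 0 h replicate 1, and FNcKO 0 h replicate 1 left out, no gene passed in edgeR (1492 had an unadjusted p under 0.05), and the adjusted p of Bst1 was 0.424. The genotype differences at the 2 times, which share no library, correlated across genes with r = 0.271 and rho = 0.221. At both times 2 genes were higher (Ece1 and Ankrd34c) and 4 lower (Bst1, Gm9199, Lbp and Serpina3h), a set named after its values were seen, where independent lists would share 0.00453 and 0.0199.

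**Figure D4:**
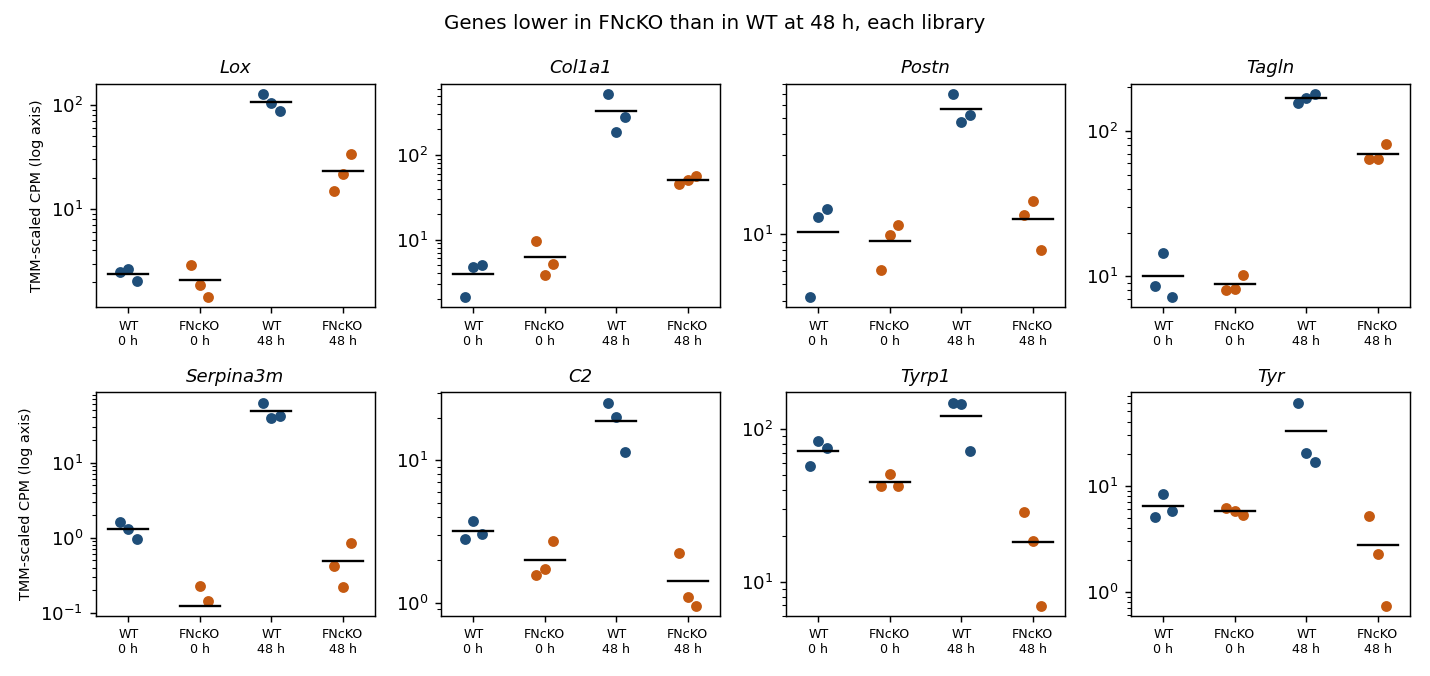
Level in TMM-scaled CPM on a log axis of 8 genes that passed between the genotypes at 48 h, each point a library and each bar the mean of 3 libraries of WT or FNcKO at 0 h or 48 h. A library with 0 counts, FNcKO 0 h in Serpina3m, is not drawn; at 48 h the WT and FNcKO libraries of each gene do not overlap.

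The difference of the 48 h responses between the genotypes asks which genes responded differently, with strain differences that are constant over time cancelled. No gene passed (edgeR's quasi-likelihood test, lowest BH-adjusted p = 0.186), while 735 had an unadjusted p under 0.05 where chance gives 728, limma-voom called 0 and DESeq2 28. Without WT 48 h replicate 3 edgeR called 1 gene (Kcne4, BH-adjusted p = 0.0277) and without FNcKO 48 h replicate 1 it called 1 gene (Igfbp2, 0.0308). Col1a1, chosen after its values were seen, had a log2 response of 6.38 (SE 0.50) in WT and 3.03 (SE 0.44) in FNcKO. The difference was −3.35 (SE 0.62, edgeR, BH-adjusted p = 0.328). It passed with DESeq2 (BH-adjusted p = 8.62e-05) and in edgeR with fiber cell content as a covariate (−3.24, BH-adjusted p = 0.0455). Of 32 matrix genes 0 passed and 7 were lower adjusted over the list alone (camera, BH-adjusted p = 7.25e-06, adjusted p = 0.0801 with an estimated correlation). Of 9 pigment cell markers 0 passed and 5 were lower adjusted over the list alone (camera, BH-adjusted p = 3.13e-10, adjusted p = 0.126 with an estimated correlation).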

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

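The genotype difference averaged over both times and the tests of flanking DNA, strain variants, paralogs, constant strain differences and pigmented cells were chosen after the result was seen. A difference between the genotypes in the response of a gene list brought the results of the next paragraph here.

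There were 10 lists that had a lower 48 h response in FNcKO than in WT by camera's test of the difference of the responses, with 0 of their genes past the threshold in edgeR. Fibrillar and matricellular matrix genes had an adjusted p of 7.253e-06 (camera with BH adjustment, adjusted p = 0.0801 with an estimated correlation) and pigment cell markers 3.134e-10 (0.126 with an estimated correlation). Glycolysis and hypoxia genes had 1.046e-05 (adjusted p = 0.126 with an estimated correlation), unfolded protein response genes 3.877e-05 (0.344) and immediate early genes 0.001437 (0.365). Smooth muscle type genes had 0.003608 (adjusted p = 0.442 with an estimated correlation), lost without WT 48 h replicate 3 (0.101) or FNcKO 48 h replicate 1 (0.161). Macrophage and monocyte markers had 0.01628 (adjusted p = 0.660 with an estimated correlation), lost without WT 0 h replicate 1 (0.301), WT 48 h replicates 1 or 2 (0.363 and 0.0536), FNcKO 0 h replicate 3 (0.168) or FNcKO 48 h replicate 1 (0.327). Corneal markers had 0.0357 (adjusted p = 0.442 with an estimated correlation), lost without WT 48 h replicate 3 (0.0979). Lens epithelial genes had 0.04131 (adjusted p = 0.442 with an estimated correlation), lost without WT 0 h replicates 1 or 2, WT 48 h replicates 2 or 3, FNcKO 0 h replicates 1 or 2 or FNcKO 48 h replicate 3 (0.0665 to 0.553). Matrix proteases and inhibitors had 0.04274 (adjusted p = 0.442 with an estimated correlation), lost without WT 0 h replicates 1 or 2, WT 48 h replicate 1, FNcKO 0 h replicates 1 or 2 or FNcKO 48 h replicate 1 (0.0506 to 0.371). With fry the matrix list (BH-adjusted p = 0.0297) and the glycolysis and hypoxia list (0.0210) passed for this difference. The unfolded protein response (fry, BH-adjusted p = 0.0883), immediate early (0.232) and smooth muscle type (0.268) lists did not.

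Averaged over both times, 70 genes differed between the genotypes (edgeR, BH-adjusted p under 0.05), 26 higher and 44 lower in FNcKO, a count that fell to 42 without WT 0 h replicate 1, 34 without WT 0 h replicate 2, 45 without WT 48 h replicate 2, 46 without FNcKO 0 h replicate 3 and 37 without FNcKO 48 h replicate 2. It was 17 without both 0 h replicate 1 libraries, 0 with the combined table column and without FNcKO 0 h replicate 1 (1282 with an unadjusted p under 0.05), 134 with the fiber content covariate, 284 with DESeq2 and 83 with limma-voom. DNA of another strain kept around the Fn1 locus cannot account for most of them, since 69 of the 70 lie more than 10 Mb from Fn1, and of 106 tested genes within 10 Mb only Igfbp2 passed (Fisher's exact test, 1-sided p = 0.401), which leaves Igfbp2 open. Reads shared between paralogs stay open for the Serpina3 genes, since 6 members together lacked 153.6 CPM in FNcKO at 48 h, while Serpina3n was at 4415 ± 925 CPM in WT and 4379 ± 1923 in FNcKO, with a 95% margin of 3421 CPM on that difference. Strain variants elsewhere in the genome cannot be told apart from an effect of the knockout, which stays open too, because every FNcKO library has the mixed background: 17 of the 70 genes had another within 1 Mb where random draws gave 7.47 (permutation p = 0.0088), and 13 with paralogs set aside where draws gave 7.39 (permutation p = 0.0713), while 0 of 4 genes known to vary between the strains passed in edgeR (1, Wdfy1, with an unadjusted p under 0.05), with log2 values from −0.28 to 0.33.

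At 48 h 3 of 32 matrix, 1 of 16 smooth muscle type and 3 of 9 pigment cell genes were lower in FNcKO, and the lists stood lower (camera, BH-adjusted p = 1.86e-10, 0.000918 and 3.61e-24, adjusted p = 0.0389, 0.365 and 0.0389 with an estimated correlation), the smooth muscle call being lost without WT 48 h replicate 3 (0.222) or FNcKO 48 h replicate 1 (0.384). A strain difference that is constant over time would give the same mean difference at both times. For the 48 matrix and smooth muscle type genes it was 0.04 on the log2 scale at 0 h and −0.57 at 48 h, a difference of 0.614 (SE 0.156). For the 9 pigment markers it was −0.43 and −2.42, a difference of 1.98 (SE 0.682). The lists were looked at because they stood lower at 48 h, so these values repeat that choice and do not exclude a constant strain difference. With an estimated correlation none of the 3 lists passed camera's test of the difference of the responses. With fry the matrix list passed for that difference (BH-adjusted p = 0.0297) and the smooth muscle list did not (0.268). Fewer pigmented iris or ciliary cells in the FNcKO 48 h libraries cannot be told apart from a change within lens cells: within the groups the slope of the 48 genes on the pigment markers was −0.139 (SE 0.107) where this explanation needs 0.237 (SE 0.0656), and the distance of 0.376 lay within the margin of 0.399 that 3 degrees of freedom allow. The distance was 0.331 against 0.446 for the matrix list, 0.465 against 0.468 for the smooth muscle list and 0.895 against 0.869, outside the margin, for the 4 members past the threshold (Col1a1, Postn, Lox and Tagln), a set chosen for the pattern that was tested first and then replaced by the whole lists. A strain difference in the response to injury and the knockout itself both stay open and untested.

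Few genes passed between the genotypes at 48 h, 35 of 14560, while the crystallin share of the 48 h libraries ran from 1.47% to 11.9%. With the fiber content within a group as a covariate 38 genes passed (edgeR, BH-adjusted p under 0.05), a count close to 35. With that covariate 943 rather than 796 genes had an unadjusted p under 0.05 at 48 h, and 42 rather than 21 genes passed at 0 h. Fn1 passed at 48 h only in this setting. A count of calls from so few libraries cannot decide how far uneven fiber cell content accounts for the low number. No biological explanation was tested for the low number.

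With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split is the 1 with the most genes past the threshold in each comparison. The real values and the highest of the other splits were 4745 and 0 for WT over time, 3611 and 0 for FNcKO over time, 35 and 1 between the genotypes at 48 h, and 21 and 0 at 0 h. In the comparisons over time every other split mixes 0 h and 48 h libraries on each side. The large difference between the times then enters the spread, so counts near 0 were to be foreseen and give no support. For the difference of the responses and the averaged genotype difference, 100 splits within each time were run, the real one and a random draw of the others. For the difference of the responses all 100 gave at least the real 0 genes (735 with an unadjusted p under 0.05, limma-voom 0, DESeq2 28), the highest being 119. No split can give fewer than 0 genes, so that result was fixed in advance and decides nothing. For the genotype difference averaged over both times 2 of the 100 splits that were run gave 70 or more, the real one included. This is a share under 0.05 of the drawn splits, although the condition written before the splits were run, that no other gives as many, was not met. The other split gave 119 genes, more than the real one, and set WT 0 h replicates 1 and 2, FNcKO 0 h replicate 2, WT 48 h replicates 2 and 3 and FNcKO 48 h replicate 1 against the rest, a structure of the samples that does not follow genotype. Photoreceptor markers, looked at afterwards, summed to 4178, 6918 and 4341 CPM in its 0 h libraries against 2152, 1526 and 1213 in the rest. At 48 h the sums were 3631, 1903 and 3249 CPM against 1211, 315 and 1977, which overlap. Whether photoreceptor content contributes to the calls of either split was not tested.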

How the results depend on the processing

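The combined table column, leaving out both 0 h replicate 1 libraries and the covariates were chosen after the data were seen; all other settings were fixed before. Every setting fixed beforehand was run, but the exact test and the fit of only the compared groups not for the difference of the responses or the averaged genotype difference. These 2 settings, DESeq2 and limma-voom were run for genes and not for gene lists, and the minimum of 5 CPM left the erythroid list without a test. A fold change of at least 2 left 2976 genes in WT and 2322 in FNcKO over time. DESeq2 called 119 genes between the genotypes at 48 h, 129 at 0 h and 28 for the difference of the responses, and the edgeR exact test 110 and 206 at 48 h and 0 h. In a fit of only the compared groups fewer libraries inform the spread, and the counts moved both ways. It called fewer genes than the main fit at 48 h (7) and in FNcKO over time (2616), and more at 0 h (30) and in WT over time (5172). Total counts called 10 genes at 0 h. The combined table column called 9 at 48 h and 0 at 0 h (1492 with an unadjusted p under 0.05), where an FNcKO library then stands among the WT libraries and is missing from the FNcKO 0 h group. Leaving out both 0 h replicate 1 libraries called 2299 genes in FNcKO over time, 14 at 48 h and 2 at 0 h, with fewer libraries. The fiber content covariate called 42 genes at 0 h and 6 for the difference of the responses, and the Xist covariate 13 at 0 h. The causes of these changes in the counts were not tested.

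With 1 library left out, the counts ran from 3209 to 5220 in WT over time, 2232 (without FNcKO 48 h replicate 3) to 4095 in FNcKO over time, 10 (without FNcKO 48 h replicate 2) to 46 (without WT 48 h replicate 3) between the genotypes at 48 h, 2 (without WT 0 h replicate 2) to 28 (without WT 48 h replicate 1) at 0 h and 0 to 1 for the difference of the responses. At 48 h between the genotypes 2 list tests changed sign. The cytokine list did so without WT 48 h replicate 1 (camera, BH-adjusted p = 0.712, and 0.000169 to 0.902 without any other 1 library). The cell cycle list did so without WT 48 h replicate 2 (camera, BH-adjusted p = 0.679, and 8.12e-12 to 0.233 without any other 1 library). The cause was not tested.

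The counts that follow take in the 5 comparisons and the added genotype difference averaged over both times. Of the list tests past the threshold, 836 kept their side and direction with a library left out, 62 lost the call and 2 changed sign, and under the other settings 751 kept it and 149 lost it. Tests not past the threshold passed in 62 and 35 cases. Calls of named genes were kept in 2070 and lost in 342 cases with a library left out, and kept in 2476 and lost in 253 under the other settings. Named genes not past the threshold passed in 5 and 26 cases. No called named gene changed sign under any of these settings. With total counts in place of TMM, 76.2% rather than 58.5% of the genes past the threshold were higher in WT over time, 82.4% rather than 60.1% in FNcKO over time, 3.57% rather than 17.1% in FNcKO than WT at 48 h and 30.0% rather than 52.4% at 0 h, with median log2 changes of all genes of 0.23, 0.29, −0.07 and −0.15. Whether equal replicate numbers mark paired libraries is not given in the sources used here, and correlations cannot settle it. In their deviations from the group means, libraries of different groups with the same number correlated with a mean r of −0.066 (−0.474 to 0.291, 18 pairs, 4 over 0.1), and those with different numbers with 0.033 (36 pairs). These means are not independent, since both rest on deviations from the same group means. With the number as a block 4184, 3048, 31, 14 and 1 genes passed in the 5 comparisons.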

Other observations

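The tests of Xist and Ddx3y were fixed before the data were seen, and all else in this part is values chosen afterwards. Levels of sex-linked genes differed between the libraries of every group. Xist, which silences an X chromosome in female cells, was at 510.5, 9.39 and 3541 CPM in the WT 0 h libraries, 925, 4.96 and 356 in the WT 48 h libraries, 13.5, 1049 and 269 in the FNcKO 0 h libraries and 500.5, 6.99 and 5.92 in the FNcKO 48 h libraries. The Y-linked gene Ddx3y, in the same order, was at 42.8, 55.5 and 0.602 CPM, 0.381, 46.6 and 28.0 CPM, 84.1, 36.0 and 48.8 CPM, and 38.4, 70.3 and 65.5 CPM. WT 0 h replicate 1, WT 48 h replicate 3, FNcKO 0 h replicates 2 and 3 and FNcKO 48 h replicate 1 held both Xist above 260 CPM and Ddx3y above 20 CPM. Neither gene passed in any of the 5 comparisons, the lowest value being that of Xist in WT over time (edgeR, BH-adjusted p = 0.588). With Xist from 9.39 to 3541 CPM within WT 0 h alone, these tests could hardly detect an imbalance of the sexes. Their outcome does not show that the groups were balanced.

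Markers of tissues next to the lens were present in all groups. The photoreceptor markers summed to 4416 ± 2392 CPM in WT at 0 h, 2248 ± 1246 in WT at 48 h, 2360 ± 1723 in FNcKO at 0 h (1526, 4341 and 1213 in the single libraries) and 1847 ± 1471 in FNcKO at 48 h (3249, 315 and 1977). The pigment cell markers summed to 251.5 ± 45.0, 352.5 ± 151, 171.5 ± 16.3 and 44.9 ± 25.9 CPM in the same order, and the vascular markers to 39.3 ± 17.0, 84.6 ± 39.1, 16.3 ± 8.47 and 55.4 ± 21.3 CPM. The 10 most abundant genes took 20.6% ± 2.98 of the counts in WT at 0 h, 11.7% ± 3.52 in WT at 48 h, 24.1% ± 7.40 in FNcKO at 0 h and 15.03% ± 2.46 in FNcKO at 48 h.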
